A study of Mus musculus with 5 samples.

How the data were processed

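Chromatin immunoprecipitation followed by sequencing was carried out on whole hearts of 12-week-old male C57BL/6 mice, per the labels. Hearts came from animals with a sham operation or from animals 4 days after transaortic coarctation (TAC), a narrowing of the aorta that loads the left ventricle with pressure. A service company performed the immunoprecipitation, the library construction and the sequencing, per the labels' protocols. The antibodies were against H2A.Z, a variant of histone H2A, and against ANP32E, a chaperone that binds H2A.Z. The 5 libraries comprised 1 library per antibody and condition and 1 input library.

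The authors deposited 2 tables, 1 per antibody, in which the intervals called in the sham and TAC libraries were merged into a common set of regions. Per the file headers, each region carries coordinates, an average signal and a peak signal for each library, a mark for whether an interval was called in that library, the number of CpG islands, and nearby genes with their distance and position. The signal values are used as deposited by the authors. How they were scaled for sequencing depth, and how the input library entered, is not given in the sources used here, so the depth behind each value is unknown and no counting interval is given. Alignment with BWA, interval calling with SICER and the mm10 build are named per the submitters' processing notes, and their versions are not given in the sources used here. Coordinates are printed as the tables give them, on mm10. Of the gene symbols in the H2A.Z and ANP32E tables, 90.2% and 91.0% matched a RefSeq symbol of the same assembly, and 67.5% and 69.0% of the gene starts implied by the listed distances lay within 100 bp of the RefSeq gene end.

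The comparison of conditions used log2((TAC + 1)/(sham + 1)) of the average signal, with a pseudocount of 1, so that the ratio understates the difference of weak regions. A region or promoter was counted as higher or lower where the ratio was at least 1.5-fold. No replicates exist in this design, so no test across animals was possible and no p-value is given; all differences describe these libraries. A promoter was the region listed for a gene with the smallest distance to its start, within 1000 bp or overlapping it. A gene-body region was any other region listed as lying within a gene. The signal of a region that serves a pair of divergent genes is the same for both.

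The following choices were made before the data were examined. Gene groups came from 22 lists with 625 entries. They covered hypertrophy stress, immediate early, sarcomere, calcium handling and ion channel, fatty acid oxidation, glycolysis, respiratory chain, ribosomal protein, spliceosome, proteasome and chaperone, cell cycle, matrix and fibroblast, endothelial, leukocyte, smooth muscle and pericyte, cardiac transcription factor, H2A.Z deposition and removal, PP2A subunit, replication-dependent histone, neuronal, liver and epithelial, and homeobox genes. For each list with at least 5 promoters, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean signal in 20 bins, and a list stood apart where its percentile was under 2.5 or over 97.5. The genes named in the text are, per antibody, the 8 highest and the 8 lowest promoter ratios in the stronger 50% of promoters without predicted or numbered loci, the 4 strongest promoters, 8 fixed genes, and the 2 highest and 2 lowest members of each list that stood apart. The 4 highest and 4 lowest sums of both ratios were added for the comparison of the proteins. Fixed genes were Anp32e, H2afz, H2afv, Ppp2ca, Nppa, Nppb, Myh6 and Myh7. Other genes are marked where they appear.

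Overlap of the tables was counted from 1 bp and set beside 100 shifts of the regions as blocks along each chromosome. Relations between the proteins were Spearman coefficients across promoters with a region in both tables. Alternatives included the peak signal, pseudocounts of 0.1 and 5, the stronger 50% of regions, ratios centred on their median, a 2-fold threshold, promoters within 5000 bp, autosomes, other ways of drawing random lists, and other definitions of overlap and pairing. Added after the data were seen were matching on CpG islands or on sham signal, counting each region only once, and restricting lists to promoters called in both libraries.

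The percentile procedure was tested on simulated data, with ratios shuffled among promoters of like signal. Of 200 unchanged lists of 20 promoters, 5.0% fell outside the central 95% among the 13762 H2A.Z promoters and 6.5% among the 5496 ANP32E promoters. A shift of 0.2 log2 placed such a list above the 97.5 percentile in 100% of simulations for H2A.Z and in 48.0% for ANP32E. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.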

Results

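H2A.Z and ANP32E occupancy was profiled in sham-operated hearts and in hearts under 4 days of pressure overload, with 1 library per protein and condition. H2A.Z marks nucleosomes at promoters and regulatory elements, and ANP32E removes it from chromatin and also inhibits protein phosphatase PP2A. The comparisons ask where each protein differs between TAC and sham hearts, and how far their positions and differences coincide. The H2A.Z table held 31098 regions, of which 27680 were called in sham and 27326 in TAC, covering 118 and 117 Mb. The ANP32E table held 8444 regions, with 7024 called in sham and 4220 in TAC, covering 13.1 and 8.97 Mb. The median average signal per region was 15.7 in both H2A.Z libraries. It was 8.26 in the sham and 7.42 in the TAC library for ANP32E, whose values spanned a narrow range from 1.0 to 18.5.

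H2A.Z at most promoters was nearly alike in sham and TAC hearts. Average signal was slightly less at replication-dependent histone, immediate early and spliceosome genes, the lists that stood apart under every alternative. Contractile, calcium-handling and stress-response genes were also slightly low and respiratory chain genes slightly high, but none of these lists held its call under every alternative. Peak values placed the contractile, stress-response and spliceosome medians slightly above 0. The 2 lowest members of the stress-response (Xirp2 and Ankrd1), calcium (Trdn and Cacna1c), respiratory chain (Cox6a2 and Cox8b) and sarcomere (Ldb3 and Tnnt2) lists all lacked a CpG island at the promoter. Signal at Xirp2, an actin-binding protein of the intercalated disc, was 12.3 in sham and 7.12 in TAC, and at Ankrd1, a stretch-responsive sarcomeric protein, it was 13.3 and 8.07. The promoter of Adrb1, the main beta-adrenergic receptor of cardiomyocytes, had 23.4 in sham and 33.4 in TAC, a 1.43-fold difference that is not counted as higher. Over all regions the median log2 ratio was 0.014 (SD 0.29), with 540 regions higher and 1218 lower in TAC, but with peak values the balance turned, to 1808 higher and 1385 lower. Over 13762 promoters in 11617 regions it was 0.035 (SD 0.16), with 60 higher and 20 lower; peak values gave a median of 0.14, with 395 higher and 34 lower.

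Most H2A.Z regions, 23908 or 76.9%, were called in both conditions. The 3772 regions called in sham only lay mostly away from promoters, with 50.4% in gene bodies and 1.8% over a CpG island. Of the 3418 regions called in TAC only, 35.9% lay in gene bodies and 9.95% over a CpG island. Gene-body regions without a CpG island had a median log2 ratio of -0.09, with 182 higher and 609 lower. The 673 gene-body regions with a CpG island had a median of 0.09, with 14 higher and 2 lower.

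Within the stronger 50% of promoters by mean signal, the largest H2A.Z ratio was at Gpr176, an orphan G protein-coupled receptor (chromosome 2, 118372146 to 118374904), where signal was 24.5 in sham and 38.0 in TAC (log2 ratio 0.61). Tmeff2, encoding a transmembrane protein with follistatin domains, followed with 24.4 and 37.1 (0.58). Adrb1 (0.50; chromosome 19, 56719674 to 56725144), Snapc4 (0.49), Arhgef26 (0.47), Dclk2 (0.47) and Dsel (0.45) were also among the highest, all over CpG islands. The lowest ratios there were smaller in size. Sertad3, a transcriptional coregulator, had 48.6 in sham and 38.2 in TAC (-0.34), and Eif4a1, the RNA helicase of translation initiation, had 36.6 and 29.4 (-0.31). The shared promoter of the tumour suppressor gene Trp53 and its neighbour Wrap53 had 46.9 and 37.7 (-0.31). Next were the shared promoters of Mdc1 and Tubb5 (-0.30), of Lrrc28 and Ttc23 (-0.30) and of Apba3 and Mrpl54 (-0.28), then Kif11, a mitotic kinesin (-0.28), and Srsf3, a splicing factor (-0.28). The strongest H2A.Z promoters differed little: 4930526I15Rik had 91.1 and 85.9, the shared Ndufa13 and Tssk6 promoter 85.2 and 80.3, the shared Enoph1 and Hnrpdl promoter 75.9 and 71.3, and Lmnb1 67.4 and 65.6. The genes of H2A.Z itself were close to 0, at 0.03 for H2afz and -0.15 for H2afv, although the latter's peak value gave 0.13. Anp32e was at -0.03 and Ppp2ca, the catalytic subunit of PP2A, at -0.06. Nppa, Nppb, Myh6 and Myh7 had no H2A.Z region at the promoter.

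Of the 21 lists that could be placed, 9 stood apart for H2A.Z, 8 of them on the low side, although few of their promoters were past 1.5-fold: 2 hypertrophy stress, 1 calcium and 1 respiratory chain gene, all lower. Sarcomere genes had a median log2 ratio of -0.09 over 14 promoters (percentile 0.26), none past 1.5-fold, with Ldb3, a Z-disc protein, at -0.39, Tnnt2, cardiac troponin T, at -0.36, and Nebl and Tpm1 both at 0.27. Calcium handling and ion channel genes had -0.08 over 25 promoters (percentile 0.045), from -0.61 at Trdn, the triadin of the calcium release complex, and -0.57 at Cacna1c, the L-type calcium channel, to 0.17 at Camk2d and 0.26 at Hrc. Hypertrophy stress genes had -0.07 over 15 promoters (percentile 0.41), from Xirp2 (-0.71) and Ankrd1 (-0.65) to Tubb6 (0.08) and Uck2 (0.18). In the stronger 50% of promoters, the remaining hypertrophy stress and calcium genes had positive medians, 0.03 (percentile 58.3) and 0.05 (percentile 72.1), so that weakly marked promoters carried these low medians. Immediate early genes, transcription factors and regulators induced within minutes of a stimulus, had -0.06 over 27 promoters (percentile 0.10). Jund stood at -0.21, Zfp36 at -0.20, Dusp2 at 0.23 and Fosl1 at 0.27. Peak values turned the sign at Jund (0.03) and Dusp2 (-0.09), but not at Zfp36 and Fosl1.

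The replication-dependent histone genes, 38 promoters in 16 regions, had the lowest list median, -0.20 (percentile 0.00), and 3 of them had a ratio above 0. Hist1h4d stood at -0.34 and Hist1h1d at -0.28, against 0.12 at Hist3h2ba and 0.13 at Hist1h4j; these genes have near-identical copies, so their values are uncertain. PP2A subunit genes had a median of -0.05 over 20 promoters (percentile 0.41), with Ppp2r5d at -0.20, Ppp2r5c at -0.17, Ppp2r1b at 0.13 and Ppp2cb at 0.29. Spliceosome genes had -0.05 over 24 promoters (percentile 0.39), with Srsf3 and Snrpa (-0.18) lowest and Snrpb (0.14) and Snrpd1 (0.22) highest. Smooth muscle and pericyte genes had -0.09 over 9 promoters (percentile 2.08), with Des at -0.26, Abcc9 at -0.16, Kcnj8 at 0.13 and Notch3 at 0.33. Among the members named for the histone, PP2A, spliceosome and smooth muscle lists, peak values turned the sign only at Hist1h4j (-0.03), Snrpa (0.03) and Notch3 (-0.10). Respiratory chain genes had 0.08 over 35 promoters (percentile 98.6), although the muscle isoforms went both ways: Cox6a2 stood at -0.62, Cox8b at -0.38 and Cox7a1 at 0.40, next to 0.22 at the complex I subunit Ndufb8. Homeobox genes had the highest median, 0.20 over 25 promoters with 24 ratios above 0, within the central range of promoters of like signal (percentile 96.8). The other lists lay inside that range, at -0.0033 for fatty acid oxidation, -0.0033 for ribosomal protein, -0.02 for cardiac transcription factor, 0.01 for H2A.Z deposition and removal, 0.03 for proteasome and chaperone, 0.03 for glycolysis, 0.05 for cell cycle, 0.07 for matrix and fibroblast, 0.07 for endothelial, 0.07 for neuronal and 0.14 for liver and epithelial genes. Only 2 of 25 leukocyte genes had an H2A.Z promoter (median 0.04). With peak values, the sarcomere, PP2A, hypertrophy stress and smooth muscle lists moved inside the central range, to percentiles of 7.99, 10.7, 2.85 and 2.80. Over all promoters the peak median was 0.14, and the medians of the sarcomere (0.05), PP2A (0.07), hypertrophy stress (0.02) and spliceosome (0.04) lists turned positive, while remaining below the medians of random lists of like signal (0.16, 0.13, 0.15 and 0.12); the calcium list was at 0. The sarcomere list was also inside it among promoters called in both libraries (9.03), the smooth muscle list with the strongest region at any distance (29.6), and the respiratory chain list with that choice (96.7) and without matching (94.7).

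**Figure D1:**
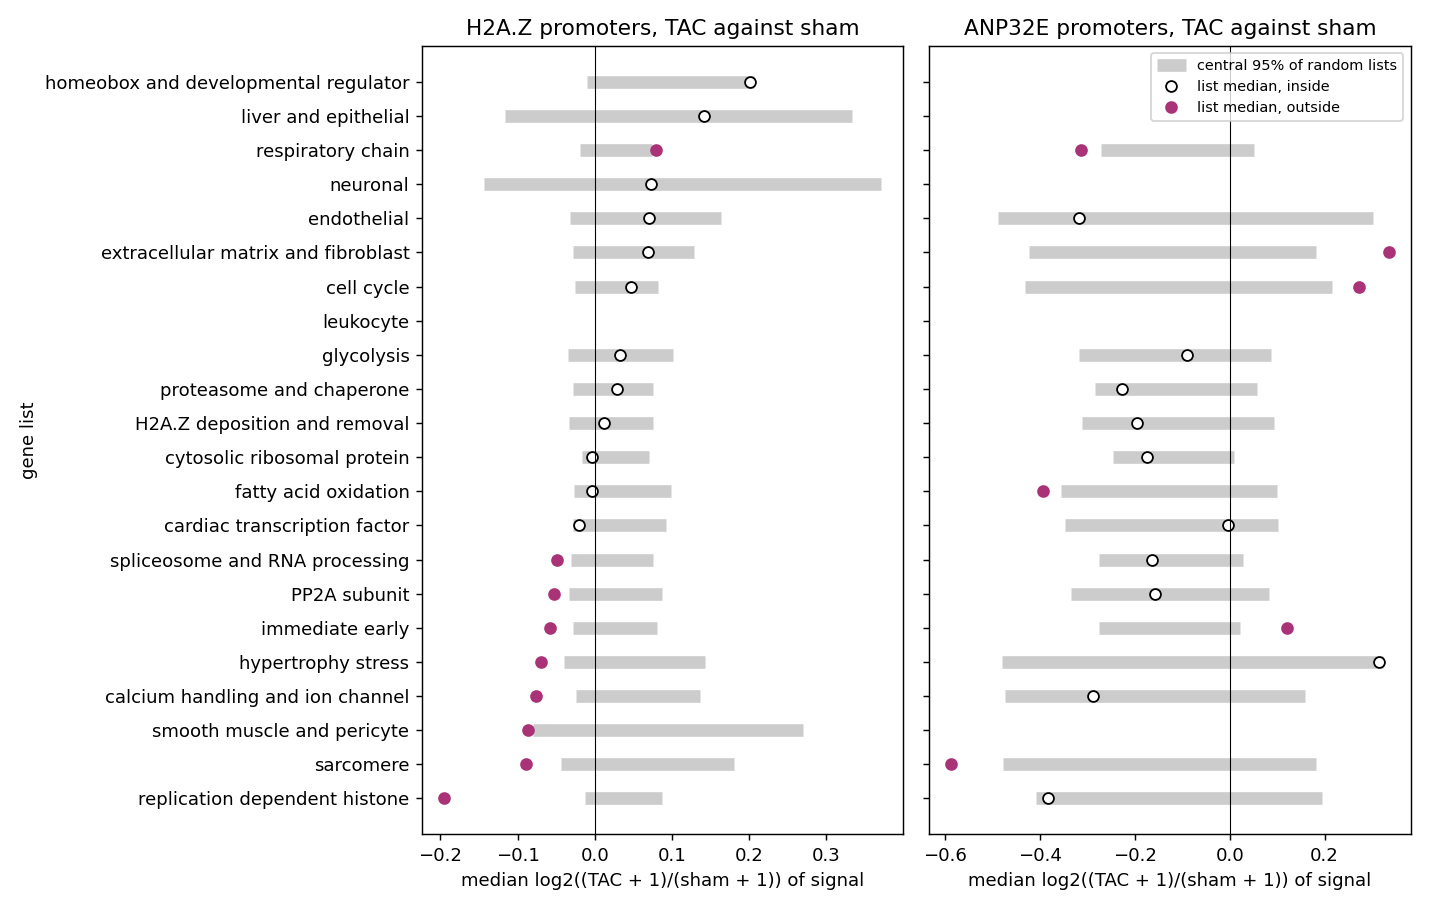
Median log2 ratio of TAC over sham for the promoters of each gene list (rows), for H2A.Z on the left and ANP32E on the right, with differing horizontal scales. Grey bars are the central 95% of random lists of the same size matched on signal, filled points are lists outside it and open points lists inside it; lists with fewer than 5 promoters have no point, and immediate early genes lie low for H2A.Z (-0.06) and high for ANP32E (0.12).

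ANP32E signal was lower in TAC over contractile genes and higher at immediate early and matrix gene promoters, against a background in which most regions were lower. The sarcomere and matrix lists could not be placed among promoters called in both libraries, where too few of their promoters remained. Fatty acid oxidation genes were also low and cell cycle genes high, but these lists stood apart under only 5 of 9 and 5 of 7 alternatives. At the promoter of Myom1, a protein of the sarcomeric M-band, signal was 8.33 in sham and 3.13 in TAC, and at Ttn, the giant sarcomeric spring titin, it was 8.80 and 4.00. At Fosb, a stimulus-induced transcription factor, it was 6.80 in sham and 11.4 in TAC, and at Timp2, an inhibitor of matrix proteases, 4.51 and 9.10. Over all regions the median log2 ratio was -0.26 (SD 0.50), with 419 higher and 2016 lower, so that 17.2% of the regions past 1.5-fold were higher. Relative to that shift, which ratios centred on their median remove, 1046 were higher and 936 lower (52.8% higher). Over 5496 promoters the median was -0.14 (SD 0.39), with 237 higher and 508 lower (31.8% higher), or 347 and 943 with peak values. Relative to the shift, 693 promoters were higher and 126 lower (84.6% higher). The shift is the median of all regions, and promoters as a whole lay above it.

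ANP32E regions were called in both conditions in only 2800 cases (33.2%), against 4224 in sham only and 1420 (16.8%) in TAC only. The regions called in TAC only lay over promoters in 60.9% and over CpG islands in 69.8% of cases, compared with 38.9% and 35.0% of those called in sham only. Gene-body regions without a CpG island had a median log2 ratio of -0.56, or -0.30 relative to the shift, with 71 higher and 807 lower. Gene-body regions with a CpG island had 0.06, with 53 higher and 23 lower. Promoter regions had -0.12 with a CpG island, or 0.14 relative to the shift, and -0.36 without one, with 16 higher and 134 lower. The regions called in both conditions had a median of -0.09.

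**Figure D2:**
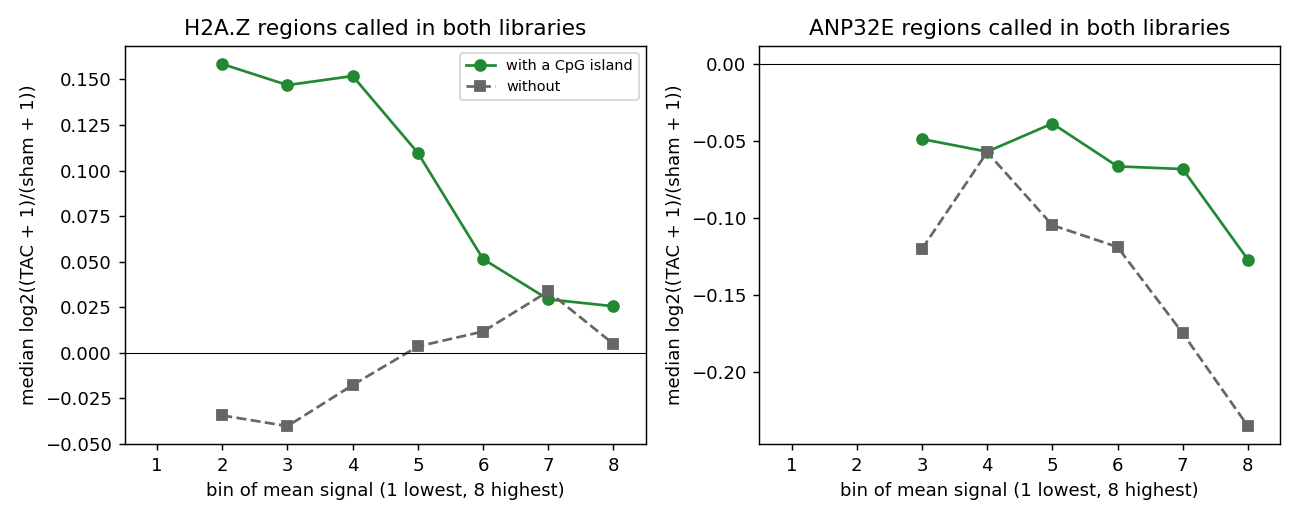
Median log2 ratio of TAC over sham for regions called in both libraries, with (circles) and without (squares) a CpG island, across 8 bins of mean signal, for H2A.Z (left) and ANP32E (right), with differing vertical scales and bins holding at least 20 regions of each kind. For H2A.Z the weakest plotted CpG-island regions stood at 0.16 and the strongest at 0.03 (0.22 and 0.12 with peak values).

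Within the stronger 50% of promoters by mean signal, the largest ANP32E ratios were at promoters called in TAC only; weaker promoters reached further in both directions. Ago2, the argonaute that executes small RNA silencing, had a signal of 5.24 in sham and a log2 ratio of 1.26 (chromosome 15, 73183573 to 73184670), and Dicer1, the nuclease that makes microRNAs, had 6.09 and 11.9 (0.87). Lemd3, an inner nuclear membrane protein, had 6.17 and 14.4 (1.10). Mfng (0.95), Vasp, an actin polymerisation factor (0.87), Abca3 (0.82), Prex1 (0.79) and E2f3, a cell-cycle transcription factor (0.73), were the others; the peak value gave only 0.08 at Prex1 and 0.34 at E2f3. The lowest ratios in the stronger 50% included Zfp384, with 14.3 in sham and 6.19 in TAC (-1.09), Sec31a, a coat protein of vesicles leaving the endoplasmic reticulum (-1.02), a promoter listed for A630020A06 and AW549877 (-0.97), Fyco1, an adaptor of autophagosome transport (-0.96), and Pdcd7 (-0.90). The small RNA genes Rnu1a1 (-1.31), Vaultrc5 (-1.06) and Rny1 (-1.06) were also among them, but Rnu1a1 and Rny1 belong to families with similar copies, in which reads are hard to place. The strongest promoters differed less, with 18.5 and 13.7 at 4930526I15Rik, 15.0 and 15.0 at Ptma and 14.1 and 15.3 at Brd2. Peak values were lower in TAC at all 3, with log2 ratios of -0.64, -0.58 and -0.19. ANP32E at the promoter of Ppp2ca was 11.6 in sham and 6.96 in TAC (-0.66, or -0.40 relative to the shift). It was 8.13 and 6.36 at Anp32e (-0.31, or -0.05), 7.97 and 5.68 at H2afv (-0.42, or -0.16) and 8.32 and 5.51 at Myh6 (-0.52, or -0.26). H2afz, Nppa, Nppb and Myh7 had no ANP32E region at the promoter.

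For ANP32E, 6 lists stood apart from random promoters of like signal. Sarcomere genes had a median log2 ratio of -0.59 over 12 promoters (percentile 0.18), or -0.32 relative to the shift; 6 were past 1.5-fold and none had a ratio above 0. Myom1 stood at -1.18 and Ttn at -0.97, and the highest ratios were at Myl4 (-0.21) and Tnnc1 (-0.15), which stood at 0.06 and 0.11 relative to the shift. Fatty acid oxidation genes had -0.39 over 17 promoters (percentile 0.92), or -0.13 relative to the shift, with 3 lower and 1 higher past 1.5-fold, from Cd36, the fatty acid transporter, at -0.81 and Pdk4, a brake on glucose oxidation, at -0.66 to Echs1 (0.05) and Slc25a20 (0.62). Respiratory chain genes had -0.31 over 23 promoters (percentile 0.49), or -0.05 relative to the shift, with 2 past 1.5-fold. They ran from Atp5o (-0.86) and Cox5a (-0.61) to Ndufv2 (0.03) and Cox5b (0.08). Peak values were lower in TAC at all of these, with -0.58 at Ndufv2 and -0.05 at Cox5b. With peak values the fatty acid oxidation and respiratory chain lists were inside the central range, at percentiles of 32.1 and 3.72, as they were among promoters called in both libraries (42.0 and 7.09). The fatty acid oxidation list was also inside it in the stronger 50% of promoters (3.34) and with each region counted once (3.71), and the respiratory chain list when matched on sham signal (14.4).

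Immediate early genes had a median ANP32E log2 ratio of 0.12 over 20 promoters (percentile 99.96), or 0.38 relative to the shift, with 13 ratios above 0 and 1 past 1.5-fold; the peak median was 0.04 (percentile 99.2). Fosb stood at 0.67 and Myc at 0.51, while Dusp1 (-0.29, or -0.03 relative to the shift) and Btg2 (-0.22, or 0.04) were lowest. Matrix and fibroblast genes had 0.34 over 6 promoters (percentile 99.8), 1 of them past 1.5-fold, with Timp2 at 0.87, Tgfbr2, a receptor of transforming growth factor beta, at 0.53, Vim at 0.25 and Timp3 at -0.20 (0.06 relative to the shift). Cell cycle genes had 0.27 over 9 promoters (percentile 98.7), 2 of them past 1.5-fold, with E2f3 at 0.73, Ccne1, cyclin E, at 0.70, Mcm2 at -0.08 (0.18 relative to the shift) and Cdk4 at -0.31. The cell cycle list moved inside the central range with peak values (percentile 90.3) and with lists matched on sham signal (68.7). The lists inside the range had medians of 0.32 for hypertrophy stress (5 promoters, percentile 97.0), -0.29 for calcium handling and ion channel, -0.09 for glycolysis, -0.17 for ribosomal protein, -0.16 for spliceosome, -0.23 for proteasome and chaperone, -0.32 for endothelial, -0.0040 for cardiac transcription factor, -0.19 for H2A.Z deposition and removal, -0.16 for PP2A subunit and -0.38 for replication-dependent histone genes. Relative to the shift, the glycolysis, ribosomal protein, spliceosome, and proteasome and chaperone lists had positive medians of 0.17, 0.09, 0.10 and 0.04. So had the cardiac transcription factor, deposition and removal, and PP2A lists, at 0.26, 0.07 and 0.11. ANP32E promoter regions as a whole had 0.12 on that scale, so a positive value there does not place a list above other promoters. No gene of the leukocyte, smooth muscle and pericyte, neuronal, liver and epithelial or homeobox lists had an ANP32E promoter.

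Beyond promoters, ANP32E lay along the bodies of several genes known for high expression in heart muscle in sham hearts, with few calls there in TAC. These gene-body regions were examined after their values were seen, and other genes had a like pattern. Arid5b had 8 of 8 gene-body regions called in sham only, and Nfia 8 of 11. Myh6, the alpha myosin heavy chain, carried 8 gene-body regions, all called in sham only, with a mean signal of 8.39 in sham and 3.78 in TAC. Atp2a2, the calcium pump of the sarcoplasmic reticulum, carried 7 such regions, all called in sham only, with 7.72 and 3.19. Of 7 gene-body regions of Cd36, 6 were called in sham only, with 8.19 in sham and 3.81 in TAC. Over all genes, 1385 of 1975 gene-body regions were called in sham only and 330 in TAC only. Among sarcomere genes, 23 of 25 gene-body regions in 10 genes were called in sham only and none in TAC only, with a median log2 ratio of -0.95. Calcium handling and ion channel genes had 24 of 26 in sham only and 1 in TAC only (median -0.78 over 11 genes), and fatty acid oxidation genes 12 of 13 in sham only (median -0.97 over 5 genes). Endothelial genes had 10 of 16 in sham only and 3 in TAC only, with a median of -0.52 over 8 genes, and cell cycle genes 4 of 9 and 3 of 9, with -0.06 over 5 genes, which became 0.04 when 1 gene was left out. Taken singly, none of these lists was outside the central 95% of gene bodies of like mean signal. The sarcomere list was at percentile 6.53, the calcium list at 37.2 and the fatty acid oxidation list at 3.13. Random gene bodies of like mean signal had medians of -0.78, -0.74 and -0.69. The mean includes the TAC value, so this matching draws random genes with ratios closer to those of the lists. For the 3 lists together, with a median of -0.92, random medians were -0.75 when matched on mean signal and -0.53 on sham signal. Part of the difference is thus shared with other genes, and how much depends on the matching. When matched on sham signal instead, the sarcomere list was outside the central 95% and the others were inside.

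**Figure D3:**
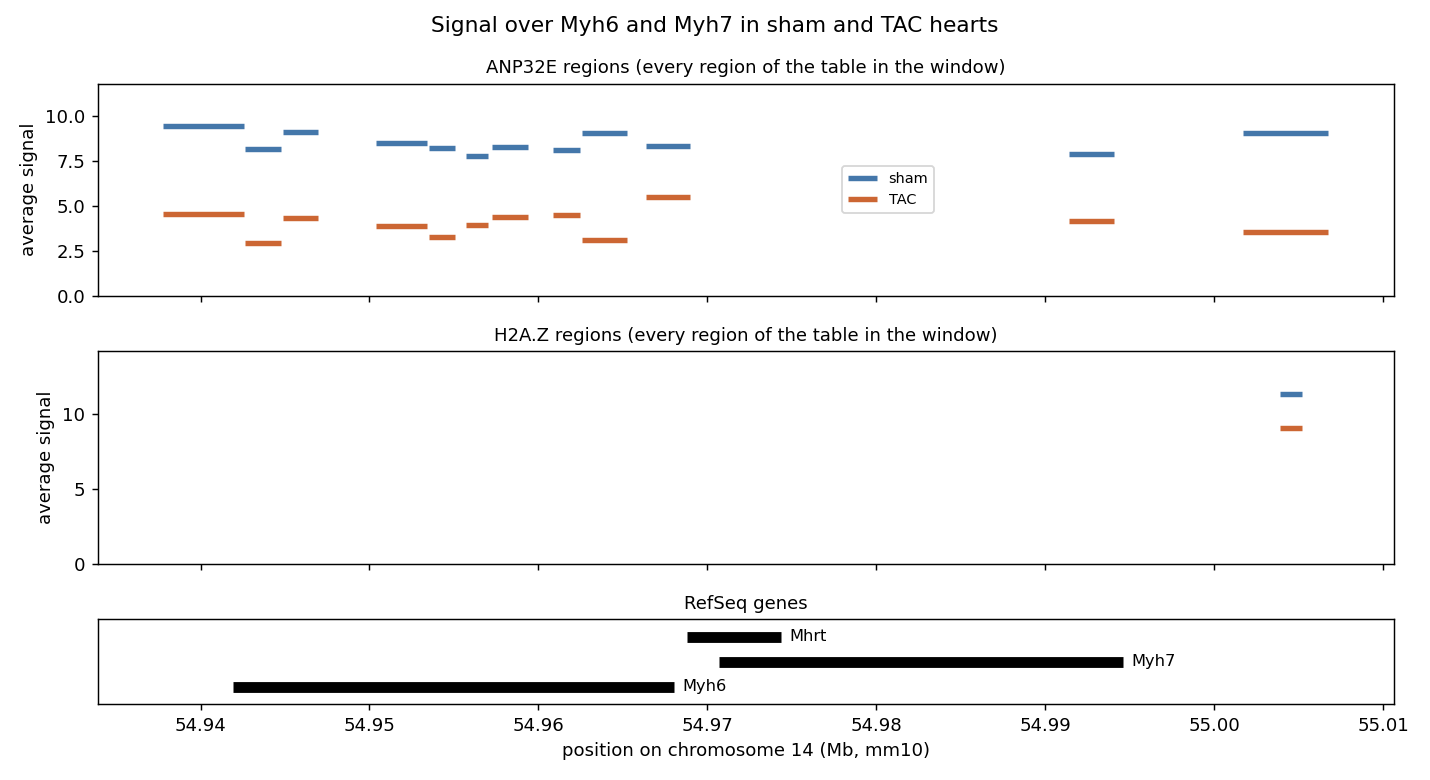
Average ANP32E (top) and H2A.Z (middle) signal of every listed region around Myh6 and Myh7 on chromosome 14 of mm10, in sham (blue) and TAC (orange), above the RefSeq gene spans; bars run from the start to the end of a region. All 12 ANP32E regions in the window were called in sham only, with signal from 7.75 to 9.42 in sham and from 2.91 to 5.51 in TAC, and the table listed 1 H2A.Z region there.

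ANP32E lay almost entirely within H2A.Z regions. Of its 8444 regions, 92.8% overlapped an H2A.Z region, against a mean of 7.58% (range 6.45 to 11.5) when regions were shifted along the chromosomes. In the other direction, 23.1% of H2A.Z regions overlapped ANP32E, against 2.00% after shifting. Shifting does not keep regions at promoters or CpG islands, so it cannot tell the overlap from a common preference for such sites. At promoter regions the share of ANP32E regions with H2A.Z was 99.3%, and in gene bodies 77.3%; Myh6 was an example of a gene body with ANP32E and no listed H2A.Z. Of 5496 genes with an ANP32E promoter, 5449 (99.1%) also had an H2A.Z promoter, where 4310 would be shared if the gene sets were independent among the 17548 genes listed. H2A.Z was stronger where ANP32E was present, with a median of 31.1 in sham and 31.0 in TAC at 4852 promoter regions with ANP32E and of 22.9 and 24.2 at 6769 without it. The median H2A.Z log2 ratio was -0.0048 with and 0.08 without ANP32E. These groups also differed in H2A.Z level and in the share over a CpG island (89.1% and 77.4%), and were not compared at matched signal.

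The differences of the proteins between TAC and sham were only loosely related across promoters. Across the 5449 shared promoters, which are not independent replicates, Spearman's rho between the H2A.Z and ANP32E log2 ratios was 0.12, and within 4 bins of H2A.Z signal it was 0.14, 0.08, 0.08 and 0.18. It was 0.04 with peak values. Across all 7840 ANP32E regions that overlapped H2A.Z, including those away from promoters, it was 0.25. Levels were more closely related, with rho of 0.34 in sham and 0.36 in TAC across shared promoters, or 0.37 and 0.59 across all overlapping regions. The highest sums of both ratios came from ANP32E alone at Dock9, a guanine nucleotide exchange factor (H2A.Z 0.01, ANP32E 1.95), and Tanc2 (0.08 and 1.71), while at Otx1, a homeobox transcription factor outside the homeobox list (0.35 and 1.60), and Fry (0.43 and 1.52) both ratios were positive. The lowest sums were at B4galt6 (H2A.Z 0.02, ANP32E -1.70), Hfe2, the muscle-expressed hemojuvelin gene (-0.39 and -1.28), Ky, a protein of muscle maintenance (-0.37 and -1.29), and Rnu1a1 (-0.30 and -1.31). ANP32E signal in sham was 1.48 at Dock9, 1.96 at Otx1, 2.19 at Tanc2 and 2.27 at Fry, against 8.56, 7.97, 9.42 and 8.40 in TAC. In TAC it was 1.65 at B4galt6 and 2.39 at Hfe2, against 7.57 and 7.26 in sham. The sizes of these ratios rest on values near the lowest of each library, 1.46 in sham and 1.0 in TAC.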

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

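The tests of the gene-body pattern were chosen after its result was seen, and those of the overall ANP32E difference before, apart from its peak values.

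Immediate early genes and respiratory chain genes stood apart on opposite sides for the proteins. For immediate early genes, the median log2 ratio of TAC over sham was -0.059 for H2A.Z and 0.12 for ANP32E, and for respiratory chain genes, which did not stand apart under every alternative for either protein, it was 0.080 for H2A.Z and -0.31 for ANP32E. Relative to the overall ANP32E shift of -0.26, these ANP32E medians were 0.38 and -0.05, beside 0.12 for ANP32E promoter regions as a whole. Each side is the difference of a single pair of libraries, and the difference between the proteins was not tested.

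ANP32E signal was lower in TAC over most regions, with a median log2 ratio of -0.26. Restricted to regions called in both libraries, the median was -0.088, between the bounds of -0.05 and -0.10 set beforehand. This restriction also drops regions that a true loss would leave uncalled in TAC, so it makes the median less negative under either reading. Selection through calling therefore cannot be told apart from a true loss. A single scale factor between the libraries would move regions with and without CpG islands alike. At matched signal they differed by 0.062 with average values, within the bound of 0.1 set for such a factor, but by 0.15 with peak values, which lies between the bounds, so this also stays open. Less ANP32E on chromatin after pressure overload, the difference the design names, remains untested beside them.

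ANP32E was lower over the bodies of sarcomere, calcium-handling and fatty acid oxidation genes. For the 3 lists together, 26 genes, the median of -0.92 stood at percentile 0.70 among genes of like mean signal, at 0.06 among genes of like sham signal and at 0.16 among regions called in sham and without a CpG island. Because these lists were picked for showing the pattern, low percentiles were to be expected. Taken singly, none was outside the central 95% of genes of like mean signal (6.53, 37.2 and 3.13). Among genes of like sham signal, the sarcomere list was outside it and the other lists were inside. With lists picked in this way, selection through calling cannot be told apart from a true loss. A smaller share of cardiomyocytes in the TAC heart was taken to raise the promoters of other cell types alike. Matrix and fibroblast promoters, some of them also active in other heart cells, exceeded endothelial ones by 0.65. This was outside the range of -0.52 to 0.48 of random pairs of lists with 6 promoters each. The comparison was chosen after the results were seen, and other cell types may rise unequally, so it cannot decide about the share of cardiomyocytes. A smaller share of cardiomyocytes, a rise of fibroblasts alone, unspecific recovery of highly transcribed chromatin in the sham library, and a true loss over active heart genes may each be involved. None of these was settled.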

How the results depend on the processing

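Matching on sham signal or on CpG islands, leaving out gene-body genes in turn, counting each region only once and restricting lists to promoters called in both libraries were chosen after the data were seen. Positions against random lists of the immediate early list (H2A.Z percentiles from 0.00 to 0.26, ANP32E from 99.2 upward), the histone (0.00 throughout) and spliceosome (0.35 to 2.47) lists for H2A.Z, and the sarcomere and matrix lists for ANP32E (at most 1.88 and at least 98.3) held with their call under every alternative that left at least 5 promoters; smaller lists gave no value. The ANP32E sarcomere and matrix lists were placed under 7 alternatives each, against 9 for immediate early genes. Restricting them to promoters called in both libraries, or to the stronger promoters, left fewer than 5. Whether their calls hold there was therefore not tested. The spliceosome median itself turned to 0.04 with peak values. Except where stated otherwise, the cause of a difference was not tested; a larger pseudocount, a stricter fold and fewer regions lower counts by construction.

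Counts of H2A.Z regions higher and lower in TAC became 102 and 231 with a pseudocount of 5, 31 and 19 in the stronger 50%, and 22 and 52 at 2-fold; with peak values 1808 were higher and 1385 lower. Promoter counts became 395 and 34 with peak values, 11 and 2 with a pseudocount of 5, 13 and 2 in the stronger 50%, and 2 and 0 at 2-fold, and 36 were lower with promoters within 5000 bp. For ANP32E the region counts were 127 and 658 with a pseudocount of 5, 86 and 288 in the stronger 50%, 1046 and 936 when centred, and 93 and 535 at 2-fold. The promoter counts were 60 and 86, 72 and 204, 693 and 126, and 43 and 51 in that order, and 943 were lower with peak values. The median over H2A.Z promoters was 0.14 with peak values. Among the stronger 50% by peak value, H2A.Z regions numbered 15458 called in both, 104 in sham only and 207 in TAC only, and ANP32E regions 1487 in sham only and 540 in TAC only.

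With peak values, 5 H2A.Z and 3 ANP32E lists stood apart, and for ANP32E 2 did in the stronger 50% and 1 among promoters called in both libraries. Calls were lost with peak values for the H2A.Z hypertrophy stress (2.85), sarcomere (7.99), smooth muscle (2.80) and PP2A (10.7) lists and the ANP32E fatty acid oxidation (32.1), respiratory chain (3.72) and cell cycle (90.3) lists. Among promoters called in both libraries they were lost for the H2A.Z sarcomere (9.03) and the ANP32E fatty acid oxidation (42.0) and respiratory chain (7.09) lists. Matching on sham signal moved the ANP32E respiratory chain and cell cycle lists to 14.4 and 68.7. In the stronger 50%, the H2A.Z hypertrophy stress (58.3) and calcium (72.1) lists turned to the other side, the cell cycle list turned low (2.00), and the ANP32E fatty acid oxidation list was at 3.34. The latter was at 3.71 with each region counted once. Without matching, the H2A.Z respiratory chain list was at 94.7, and with the strongest region at any distance it was at 96.7 and the smooth muscle list at 29.6. Leaving out each gene in turn turned the sign of 3 gene-body medians of 5 genes each: the H2A.Z hypertrophy stress list went as low as -0.040 from 0.083, the H2A.Z glycolysis list as high as 0.0092 from -0.20, and the ANP32E cell cycle list as high as 0.040 from -0.062; none of them stood apart.

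The share of ANP32E regions over H2A.Z was 92.2% with overlap of 50% of the region, 96.8% in the stronger 50% of both tables, 97.8% with both tables restricted to regions called in both conditions and 77.3% for gene-body regions. The share of H2A.Z regions over ANP32E was 24.99% in the stronger 50% of both tables and 11.1% with both tables restricted to regions called in both conditions; restricting H2A.Z alone gave 28.9%. With all overlapping regions paired, not only promoters, rho was 0.25 for the differences and 0.59 for the levels in TAC. Of the ratios of named promoters, none past 1.5-fold changed sign. Each ratio was compared with its value under peak signal, centring and the larger pseudocount, and the following counts are of these comparisons. In 194 comparisons for H2A.Z and 147 for ANP32E the ratio moved by less than the SD across promoters, against 25 and 18 with a larger move. Centring moves every ratio of a protein by the same amount, below that SD, so its comparisons count as unmoved by construction. The limit that depth sets is unknown, but 48.0% of simulated ANP32E lists shifted by 0.2 were recovered against 100% for H2A.Z.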

Other observations

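The tests of the CpG-island pattern were chosen after the result was seen, as were the gene-body values.

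Homeobox and developmental regulator genes, mostly silent in the adult heart, carried weak H2A.Z, with mostly positive ratios in TAC. Their promoter signal had a median of 14.9 in sham and 18.3 in TAC, and 24 of 25 promoters had a ratio above 0, 1 of them past 1.5-fold. Their gene-body regions, 12 in 8 genes, had a median log2 ratio of 0.28 at percentile 99.8 of gene bodies of like signal, and none of the 8 genes was below 0. CpG islands were not matched there, and H2A.Z gene-body regions had a median of 0.09 with an island and -0.09 without one. The promoter list, with a median of 0.20, was inside the central range, at percentile 96.8, since random promoters of like signal also had a positive median (0.10), and at 82.3 when matched on sham signal. None of these 38 genes had an ANP32E promoter.

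The share of genes with a region at the promoter varied among the lists and was not tested. An H2A.Z promoter was present for 27 of 28 immediate early genes, 35 of 39 respiratory chain genes, 25 of 38 homeobox genes, 38 of 63 histone genes, 9 of 15 smooth muscle and pericyte genes and 14 of 28 sarcomere genes, and for 5 of 20 neuronal, 6 of 20 liver and epithelial and 2 of 25 leukocyte genes. ANP32E reached 35 of 45 ribosomal protein genes and 20 of 28 immediate early genes. Its highest list median in sham was 10.8 at spliceosome genes.

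Over all regions, weak CpG-island regions had more H2A.Z in TAC than weak regions without an island, and strong ones hardly differed from other strong regions; whether the homeobox values belong to this was not settled. Among regions called in both libraries, CpG-island regions exceeded the others by 0.18 in signal bins 2 to 4 (bootstrap standard error over regions 0.013) and by 0.17 with peak values (0.024), so the selection that calling adds is not enough by itself. The difference was 0.03 in bins 6 to 8, lower by 0.15 (standard error 0.014), and with peak values 0.04, lower by 0.13 (0.025). A single recovery factor for all CpG islands would give like differences in weak and strong bins, unlike the values in these libraries. This contrast is the one that defined the pattern, so it is no independent test of such a factor. The standard errors cover regions and not libraries. With peak values, strong CpG-island regions also had positive medians, 0.16, 0.15 and 0.12 in bins 6 to 8, close to the 0.10, 0.14 and 0.10 of the others. A dependence of recovery on GC content that varies with signal was not tested, and a spread of H2A.Z over weak CpG islands under pressure overload stays open as a hypothesis.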
